A study of Spinacia oleracea with 24 samples.

How the data were processed

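Poly-A RNA of spinach leaves (cultivar Space) was sequenced from directional dUTP libraries on a NovaSeq X Plus, per the labels' protocols. The 24 libraries come from 48-day-old plants at 200 ppm (HN) or 50 ppm (LN) nitrogen and 8 h of light per day, 3 plants at each of 4 times. The labels state 3 independent plants and a single day of collection, and whether a replicate number follows the same plant over the day is not given in the sources used here. HISAT2, RSEM and DESeq2 version 1.20.0 are named per the submitters' processing notes, with no role stated for each. The reference is Sp75, per the title of the series.

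The deposited values are FPKM, fragments per kilobase of the gene length listed in the same table and scaled for library size, per the file headers. Each deposited FPKM value times the gene length was a whole multiple of 1 step per library (100.0% of values within a tolerance of 0.01), from which whole fragments were recovered. The libraries held 18369094 to 25252705 such fragments. The steps show that the authors scaled the libraries by median-of-ratios size factors (largest deviation 0.01%), not by the library total. The table holds 25494 genes and 1 blank line, and 17585 genes carry a Swiss-Prot protein name in the table, which is the source of the symbols used. These names come from sequence similarity to proteins of other species. Of the genes, 15704 lie on 6 named chromosomes and the others on scaffolds. No ID matched the reference gene table (0 of the table's IDs), so coordinates and names are those of the deposited table. The counting of reads shared between near-identical genes is not stated, so values of single members of the antenna, Rubisco small subunit and xyloglucan enzyme families are uncertain. No pair of replicates was close to a duplicate (lowest chi-square per degree of freedom 28.9).

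Genes with an FPKM of at least 1 in at least 3 of the 24 libraries were tested, 18110 in all. Tests used limma version 3.58.1 in R version 4.3.3 on log2(FPKM + 1), with 8 group means, 16 residual degrees of freedom and moderated variances with a trend, and Benjamini-Hochberg adjusted p under 0.05. The 24 libraries share the estimate of spread. The contrasts were LN minus HN at each time and averaged over the times, their interaction with time, the change over the 4 times within each nitrogen level, the middle of light minus the middle of dark, and the end of light minus the end of dark. The p-values measure the spread between the plants sampled, and they treat all plants as independent. Results "adjusted over the list alone" use the members of that list only.

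Before the data were examined, 32 gene lists were written from protein names, covering the clock, nitrogen, carbon, photosynthesis, stress and marker genes of other cell types. The nitrate transport list takes NRT and NPF family members, slow anion channels and CLC-a by name. Whether each member carries nitrate was not checked. Matching dropped 13 genes by name, 1 list had no matching gene, and 31 lists with at least 5 tested members gave 279 list tests over 9 contrasts. List tests used limma's camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry. The preset gave 34 calls. Of them, 0 held with an estimated correlation and 13 were also called by fry, which does not compare a list with the other genes.

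The rule for the genes named was also fixed then. It takes members of the clock, nitrate transport and assimilation lists, the 2 members with the smallest adjusted p of each other list (mean FPKM of at least 5), and the 5 highest and 5 lowest changes among passing genes with a named protein and a mean FPKM of at least 5. For the averaged nitrogen effect these had 1 sign at all 4 times, and for F tests the 10 smallest adjusted p were used.

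The tests were tried on simulated fragments with known changes. For nitrogen at the end of dark (17964 genes), 43% of 2-fold and 88% of 4-fold changes were recovered, and 3.7% of 136 calls were false. For averaged nitrogen (17989 genes) the recovered shares were 93% and 99%, with 5% of 202 calls false. The simulation changed only genes with a mean FPKM of at least 5. It gave every group the same spread per gene and drew genes independently, without time effects or outlying libraries. These shares may therefore not carry over to the real libraries. Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, a common sum of FPKM in each library, median-of-ratios scaling, only the compared groups in the fit, robust moderation, a 2-fold threshold, the replicate number as a block, and each library left out. Chosen after seeing the data were leaving out the 3 libraries farthest from their groups, array weights, voom on the recovered fragments, and a replicate block within the end of dark.

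Whether replicate numbers pair the libraries was checked from the correlation of deviations from the group means. Over 16 pairs of groups the same-number correlations ran from -0.45 to 0.46. In 1 pair of groups, HN and LN at the end of dark, all 3 were above 0.1, so the end of dark was also fitted with the number as a block over those 6 libraries, while the values reported treat the plants as independent. Figures were drawn in Python version 3.11.15 with matplotlib version 3.10.9.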

Results

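Leaves of 48-day-old spinach (Spinacia oleracea, cultivar Space) were sampled at 4 times of the daily cycle from plants given 200 ppm nitrogen (HN) or 50 ppm nitrogen (LN), with 8 h of light per day. The times were the end of the dark period (T1), the middle of the light period (T2), the end of the light period (T3) and the middle of the dark period (T4). Each of the 8 combinations of nitrogen level and time held 3 plants, which gives 24 messenger RNA libraries. The libraries held between 18369094 and 25252705 fragments assigned to genes, as recovered from the steps of the FPKM values (fragments per kilobase, scaled for library size). Of 25494 genes in the table, 18110 were expressed highly enough to be tested, and 17091 were above 0 in every library. Values below are mean FPKM ± SD with n = 3 unless stated otherwise, and fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

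The title of the series names the daily regulation of the leaf transcriptome at differing nitrogen supply, so the time of day within each nitrogen level is given first. The core clock genes cycled strongly at both nitrogen levels. LHY (Spo01117, chromosome 2, 59058703 to 59070547, of the Sp75 genome), the morning transcription factor of the plant clock, stood at 1470 ± 492 FPKM at the end of dark in HN and at 11.9 ± 2.1 at the end of light, and at 1180 ± 253 and 17.5 ± 7.25 in LN. GI (GIGANTEA, Spo04360), which acts in the evening, ran the other way, from 3.42 ± 1.94 at the end of dark to 66.7 ± 6.61 at the end of light in HN, and from 7.12 ± 2.61 to 85.9 ± 21.7 in LN. APRR1 (Spo08124), the spinach gene named after the evening repressor also called TOC1, was lowest in the middle of light, at 3.48 ± 0.522 in HN and 3.38 ± 1.59 in LN, against 79.4 ± 15.6 and 65.5 ± 37.5 in the middle of dark. ADO3 (Spo25748), which carries the name of a blue-light receptor of the flowering pathway, was at 51 ± 13 in HN and 80.9 ± 28.2 in LN at the end of light and below 5 FPKM on average at the other 3 times.

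Of the 24 tested members of the circadian clock list, 20 changed with time of day in HN and 18 in LN (20 and 19 when adjusted over the list alone). In HN, 6 of the passing members had their highest mean at the end of dark, 4 in the middle of light, 6 at the end of light and 4 in the middle of dark. In LN the same classes held 8, 1, 6 and 3. None of the 24 members differed between nitrogen levels in its daily change at an adjusted p under 0.05. Among genes with a named protein and a mean FPKM of at least 5, those with the smallest adjusted p in limma's moderated F test included LNK2 (Spo06774, 1.4e-12 in HN and 1.2e-11 in LN), LHY (3.5e-12 and 4.2e-11) and LNK1 (Spo07301, 6.6e-12 and 5.1e-11), all of the clock. Beside them stood MIP1B (Spo03899, a B-box domain protein, 1.4e-11 and 4.2e-11) and ASR1 (Spo20053, named after abscisic stress and ripening, 1.5e-10 and 2.9e-10). Among the CDF, CONSTANS-like and PIF genes that act downstream of the clock, 13 of 16 changed in HN and 13 of 16 in LN.

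**Figure D1:**
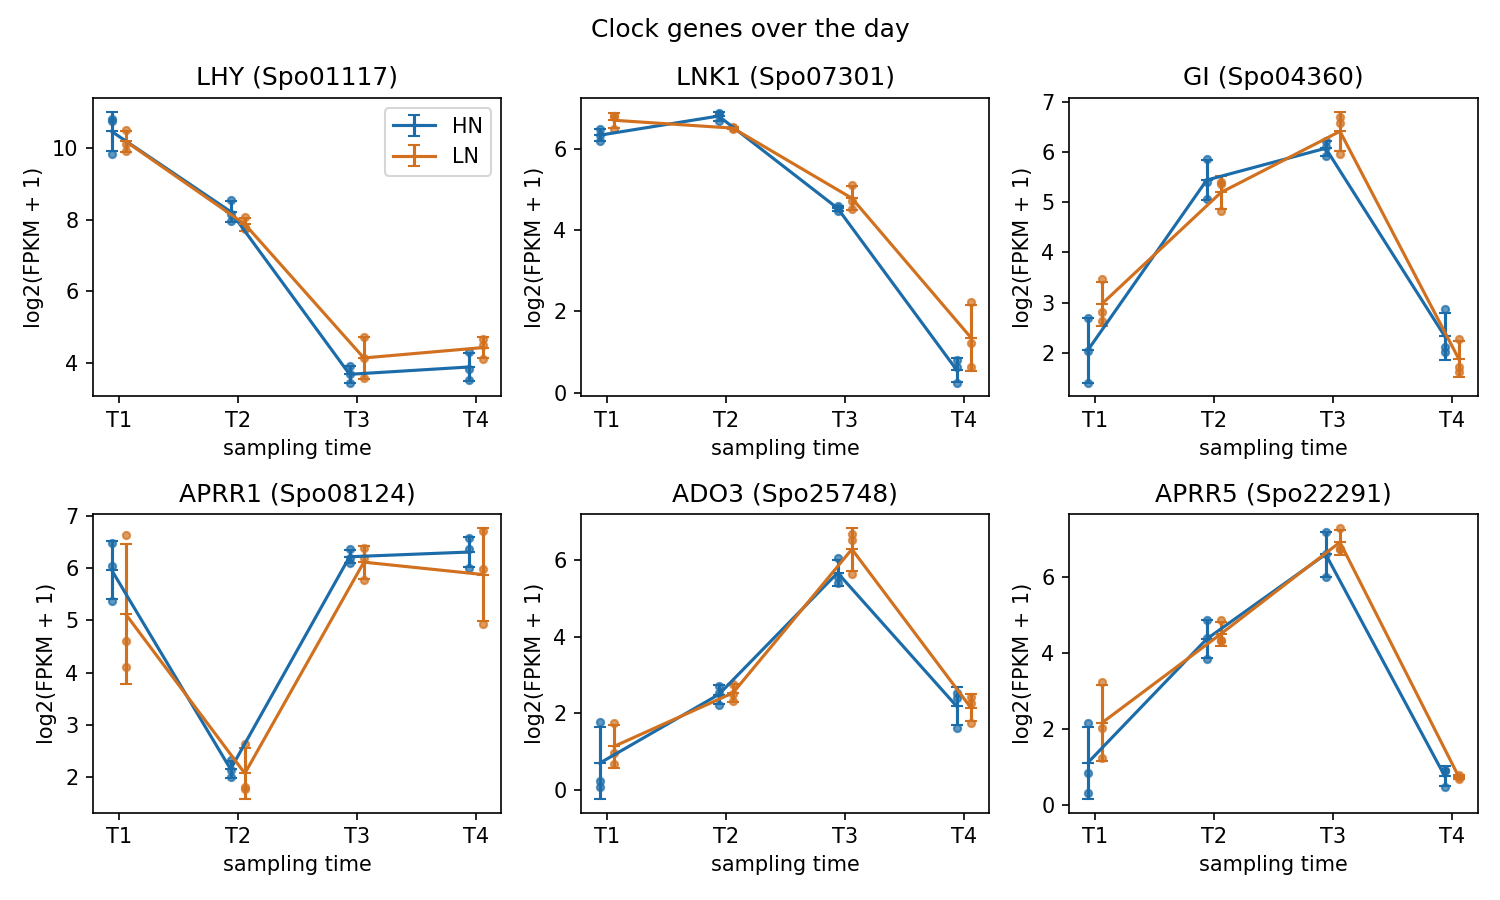
Levels of 6 clock genes as log2(FPKM + 1) over the 4 sampling times, T1 at the end of dark, T2 in the middle of light, T3 at the end of light and T4 in the middle of dark. Small points are single plants, lines join the means of 3 plants, and error bars are 1 SD; the lines of HN and LN follow each other, with LHY highest at T1 and GI and ADO3 highest at T3.

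Over all tested genes, 7053 (38.9%) changed with time of day in HN and 5197 (28.7%) in LN at an adjusted p under 0.05. With only the libraries of that nitrogen level in the fit, the counts were 7967 in HN and 2736 in LN. The end of dark was the most frequent time of the highest mean, with 2471 genes in HN and 2041 in LN. The middle of light held 1630 and 860 genes, the end of light 1762 and 1545, and the middle of dark 1190 and 751. These classes use the deposited scaling and were not counted with a common sum of FPKM. That sum lowered the middle of light against the middle of dark (median log2 change of -0.352 in HN and -0.22 in LN). Both tests were passed by 3737 genes, against 2024 for independent lists of these sizes. The tests share each gene's estimate of spread, so 2024 may be too low a baseline. Of the 3737 genes, 69.1% peaked at the same time at both nitrogen levels, against 28.4% expected from the class sizes. The median correlation of the HN and LN profiles over the 4 times was 0.93 across these genes, which are not independent replicates. A further 3316 genes passed in HN alone, and 1 of them had a nitrogen effect that differed between times in the interaction test. Of the 1460 genes that passed in LN alone, 6 did.

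From the middle of dark to the middle of light, 10 of 22 light-harvesting antenna genes rose in HN and 13 in LN. The antenna proteins, which bind chlorophyll and feed the photosystems, include Spo03024 (a chlorophyll a-b binding protein), which went from 55.1 ± 55.5 to 7410 ± 1880 FPKM in LN, a log2 change of 7.79 (SE 0.74, adjusted p = 1.5e-06). Its neighbour Spo03025 rose by 8.0 on the log2 scale in LN and by 4.90 in HN. GUN4 (Spo20278), a tetrapyrrole-binding regulator of chlorophyll synthesis, rose by 2.97 in HN and 3.42 in LN, and a chloroplast fructose-bisphosphate aldolase of the Calvin cycle, FBA2 (Spo18028), by 5.60 and 5.76. The Calvin cycle list as a whole had no call, with 1 of 26 rising and 1 falling in HN (camera adjusted p = 0.64) and 1 rising and 0 falling in LN (camera adjusted p = 0.44), likewise when adjusted over the list alone. HD3A (Spo25173), named after the rice florigen, rose by 4.27 and 4.13, and HSP70-4 (Spo17157), a heat shock chaperone, by 5.07 and 4.78. EFL1 (Spo11195), an evening clock gene of the ELF4 family, fell by 5.87 in HN and by 5.82 in LN, and SPS1 (Spo09591), a sucrose-phosphate synthase, fell by 1.33 and 1.43. GLT1 (Spo02549), an NADH-dependent glutamate synthase, fell by 1.45 and 1.64.

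In HN, 10 of 22 antenna genes rose and 0 fell (11 and 0 when adjusted over the list alone), with a list median of 1.10 and a camera adjusted p of 0.0004. In LN, 13 rose and 0 fell (16 and 0), with a median of 2.20 and a camera adjusted p of 5.6e-13. Of 55 genes of the nitrate transport list, 15 rose and 1 fell in HN (16 and 2 when adjusted over the list alone, camera adjusted p = 0.007), among them NPF2.13 (Spo25744, 2.04) and NPF4.6 (Spo25782, 1.91). In LN 4 of the 55 rose and 1 fell, without a list call (5 and 1 when adjusted over the list alone, camera adjusted p = 0.23). Chlorophyll synthesis rose as a list in LN, with 9 of 26 members higher and 0 lower (11 and 0 when adjusted over the list alone, camera adjusted p = 2.8e-06), whereas in HN 4 rose and 0 fell without a list call (4 and 0, camera adjusted p = 0.21). Photosystem subunits rose as a list in HN (7 of 46, 2 when adjusted over the list alone, camera adjusted p = 0.021) and in LN (11 of 46, 16 when adjusted over the list alone, camera adjusted p = 2.4e-05). Flavonoid and phenylpropanoid genes rose as a list in both (11 of 40 in HN, camera adjusted p = 0.049, and 5 of 40 in LN, camera adjusted p = 0.0092), with CYP75B137 (Spo11399), a flavonoid hydroxylase, at 2.20 and 1.86. Adjusted over the list alone, 11 flavonoid genes rose in HN, and 8 rose and 1 fell in LN. Heat shock genes (10 of 61 rose and 1 fell, 11 and 3 when adjusted over the list alone, camera adjusted p = 0.010), cell division and histones (5 of 88 rose and 3 fell, 6 and 3, camera adjusted p = 0.0094) and starch synthesis (3 of 15 rose and 0 fell, 5 and 0, camera adjusted p = 0.047) rose as lists in LN. In HN the same lists had no call: 16 heat shock genes rose and 3 fell (16 and 3, 0.057), 4 cell division and histone genes rose and 13 fell (3 and 6, median -0.44, 0.096), and 4 starch synthesis genes rose and 1 fell (4 and 1, 0.27). Of all these lists, the difference between HN and LN in this change was tested for the antenna alone. Its unadjusted camera p was 2.3e-05 with the preset correlation and 0.22 with an estimated correlation. This difference was not among the contrasts planned for the lists. It was not repeated without LN_T4 replicate 3, whose mean log2 antenna level of 6.28 was low. In the middle of light the levels were alike, at 9.79, 10.08 and 9.77 in LN and 9.73, 9.87 and 10.03 in HN. Among members with a mean FPKM of at least 5, the LN values of heat shock, cell division and starch synthesis were 0.092, 0.11 and 0.096. Each of these list calls was lost with an estimated correlation between genes (adjusted p = 0.99 with an estimated correlation). The photosystem call in HN ended without HN_T2 replicate 2 (0.057) or HN_T2 replicate 3 (0.091), the flavonoid call in LN without LN_T2 replicate 2 (0.086), and the flavonoid call in HN when any of 14 libraries was left out (at most 0.11, without HN_T2 replicate 2) or the replicate number was a block (0.058). The histone call in LN ended without LN_T2 replicate 1 (0.054) or LN_T4 replicate 3 (0.20). The starch call in LN ended with the block (0.055), without LN_T4 replicate 1 (0.13), LN_T2 replicate 2 (0.098) or LN_T4 replicate 3 (0.090), and at 0.050 to 0.054 without HN_T1 replicate 1, HN_T2 replicate 2, HN_T3 replicate 2, LN_T1 replicate 3 or LN_T3 replicate 2.

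In this contrast 4284 genes passed in HN (2270 higher and 2014 lower) and 1387 in LN (782 higher and 605 lower). Rescaling the libraries to 1 common sum of FPKM moved the median of all genes to -0.352 in HN and -0.220 in LN, and the share of higher calls from 53.0% to 16.7% and from 56.4% to 24.2%, so the balance of directions depends on the scaling. The HN count was 2534 without HN_T2 replicate 1 and 2699 without HN_T4 replicate 3. The LN count was 756 without LN_T2 replicate 1, 543 without LN_T2 replicate 2, 470 without LN_T4 replicate 1 and 432 with only the LN groups of this contrast in the fit, where the same fit in HN gave 3750. It was higher without the 3 libraries farthest from their groups and with array weights. The median SD in the middle of dark was 0.277 in LN and 0.21 in HN, and in the middle of light 0.238 and 0.28. The difference in counts between HN and LN was not tested, so a weaker day change in LN is not shown.

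From the end of dark to the end of light, starch synthesis genes rose as a list, and the morning clock genes LHY and RVE8 fell. SS1 (Spo02503), a starch synthase, rose by 2.88 (SE 0.26, adjusted p = 2.1e-07) on the log2 scale in HN and by 2.43 in LN, and SBEI (Spo06399), a starch-branching enzyme, by 2.97 and 2.16. Of 15 tested starch synthesis genes, 9 rose and 1 fell in HN (9 and 1 when adjusted over the list alone, camera adjusted p = 0.0066), and 5 rose and 0 fell in LN (5 and 0, camera adjusted p = 0.023), calls that were lost with an estimated correlation (adjusted p = 0.99 with an estimated correlation). The LN value was 0.13 without LN_T1 replicate 2, 0.054 without LN_T3 replicate 2 and 0.28 without the 3 libraries farthest from their groups. BAM9 (Spo09821), an inactive beta-amylase, fell by 4.10 in HN and 3.12 in LN. NIA (Spo23607), nitrate reductase, the enzyme that reduces nitrate to nitrite, fell from 1240 ± 347 to 158 ± 68.8 FPKM in HN and from 762 ± 143 to 220 ± 70.7 in LN, log2 changes of -3.0 (SE 0.42, adjusted p = 2.6e-05) and -1.82 (SE 0.42, adjusted p = 0.0033). The ammonium transporter AMT1-3 (Spo21031) rose by 2.49 in HN and 4.58 in LN.

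The fall of LHY was -6.78 in HN and -6.05 in LN, and that of RVE8 (Spo04754), a related morning factor, -3.75 and -3.31. Of the 24 clock genes, 8 rose and 9 fell in HN (8 and 11 when adjusted over the list alone, camera adjusted p = 0.61) and 6 rose and 9 fell in LN (6 and 9, camera adjusted p = 0.62), so the list moved both ways. COL15 (Spo19195) of the CONSTANS-like family rose by 5.74 and 5.43, whereas COL2 (Spo12296) fell by 3.73 and 4.03. The highest changes among named proteins were those of Spo28197, an antimicrobial peptide, at 8.65 in HN and 8.80 in LN, and ASR1, at 6.71 and 6.51. NYC1 (Spo18805), a chlorophyll b reductase, rose by 3.16 and 2.27, while BT3 (Spo14346), of the BTB and TAZ domain family, fell by 3.12 and 2.83. Photosystem genes rose as a list in LN (6 of 46, 0 when adjusted over the list alone, camera adjusted p = 0.0016) and the CDF, CONSTANS-like and PIF genes fell (9 of 16 fell and 2 rose, likewise when adjusted over the list alone, camera adjusted p = 0.023), both at 0.99 with an estimated correlation. Cell division and histones rose as a list in LN (15 of 88 rose and 7 fell, 14 and 7 when adjusted over the list alone, camera adjusted p = 0.025, and 0.99 with an estimated correlation), at 0.096 without LN_T1 replicate 2, 0.061 without LN_T1 replicate 3, 0.41 without LN_T3 replicate 3 and 0.74 without the 3 libraries farthest from their groups. The photosystem list, the CDF, CONSTANS-like and PIF list and the cell division list had no call in HN. The difference between HN and LN was not tested for them, so these changes are not shown to be particular to LN. In all, 5925 genes passed in HN (2837 higher and 3088 lower) and 4706 in LN (2207 higher and 2499 lower). The HN balance turned with a common sum of FPKM (2858 higher and 2417 lower) and among changes of at least 2-fold (1495 higher and 1449 lower). With only the 2 compared groups in the fit the counts were 6491 in HN and 1583 in LN. This difference in counts between HN and LN was not tested.

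Nitrogen supply was compared at each time and as the average over the 4 times, 12 libraries against 12. Averaged over the day, LN leaves carried less mRNA of nitrite reductase and more of cytosolic glutamine synthetase and ammonium transporters. NIR (Spo21339), which reduces nitrite to ammonium in the chloroplast, was lower in LN by a log2 change of -1.0 (SE 0.18, adjusted p = 0.0022); at the end of dark it stood at 536 ± 112 FPKM in HN and 260 ± 51.5 in LN. A glutamine synthetase named as the nodule isozyme (Spo01186) was higher in LN, by 1.54 (SE 0.31, adjusted p = 0.0035), as were GLN1-1 (Spo17102, 0.84), AMT1-2 (Spo24676, 1.41), AMT3-1 (Spo20483, 1.39) and AMT1-1 (Spo05791, 0.77). Nitrate reductase did not pass, at -0.21 (SE 0.21, adjusted p = 0.53). Of 37 genes of nitrate and ammonium assimilation, 6 rose, 4 fell and 27 did not pass (8 rose and 4 fell when adjusted over the list alone).

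Of 55 genes of the nitrate transport list, 9 rose in LN, 2 fell and 44 did not pass (9 and 2 when adjusted over the list alone, median 0.18). The list holds NRT and NPF family members and anion channels by name, so its shift is not shown to be one of nitrate transport. The camera adjusted p was 0.029, and 0.99 with an estimated correlation; it rose to 0.051 without LN_T2 replicate 2 or LN_T4 replicate 3, to 0.054 without LN_T2 replicate 3 to 0.074 without LN_T3 replicate 2, and to 0.13 among members with a mean FPKM of at least 5. NPF7.3 (Spo23405), named after a transporter that loads nitrate into the xylem, rose by 1.70 (SE 0.33, adjusted p = 0.0029) and NPF6.3 (Spo26413), named after the dual-affinity nitrate transporter, by 1.65. Among 17 nitrogen signalling regulators, 3 rose and 5 fell, with NLP2 (Spo21931), of the family of nitrate-responsive NIN-like factors, at 1.10 (SE 0.20, adjusted p = 0.0022) and HHO3 (Spo04617), a relative of nitrate-induced repressors, at -1.59 (SE 0.29, adjusted p = 0.0022). In the list of starvation peptides and glutaredoxins, 2 of 28 rose and 6 fell (2 and 11 when adjusted over the list alone). Its camera adjusted p was 0.029, and 0.99 with an estimated correlation; it was 0.069 without LN_T2 replicate 2 0.075 without LN_T3 replicate 2, and 0.29 among members with a mean FPKM of at least 5. Against the direction of the list, GRXS9 (Spo18878) rose by 1.69 and GRXC6 (Spo06088) by 1.58.

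**Figure D2:**
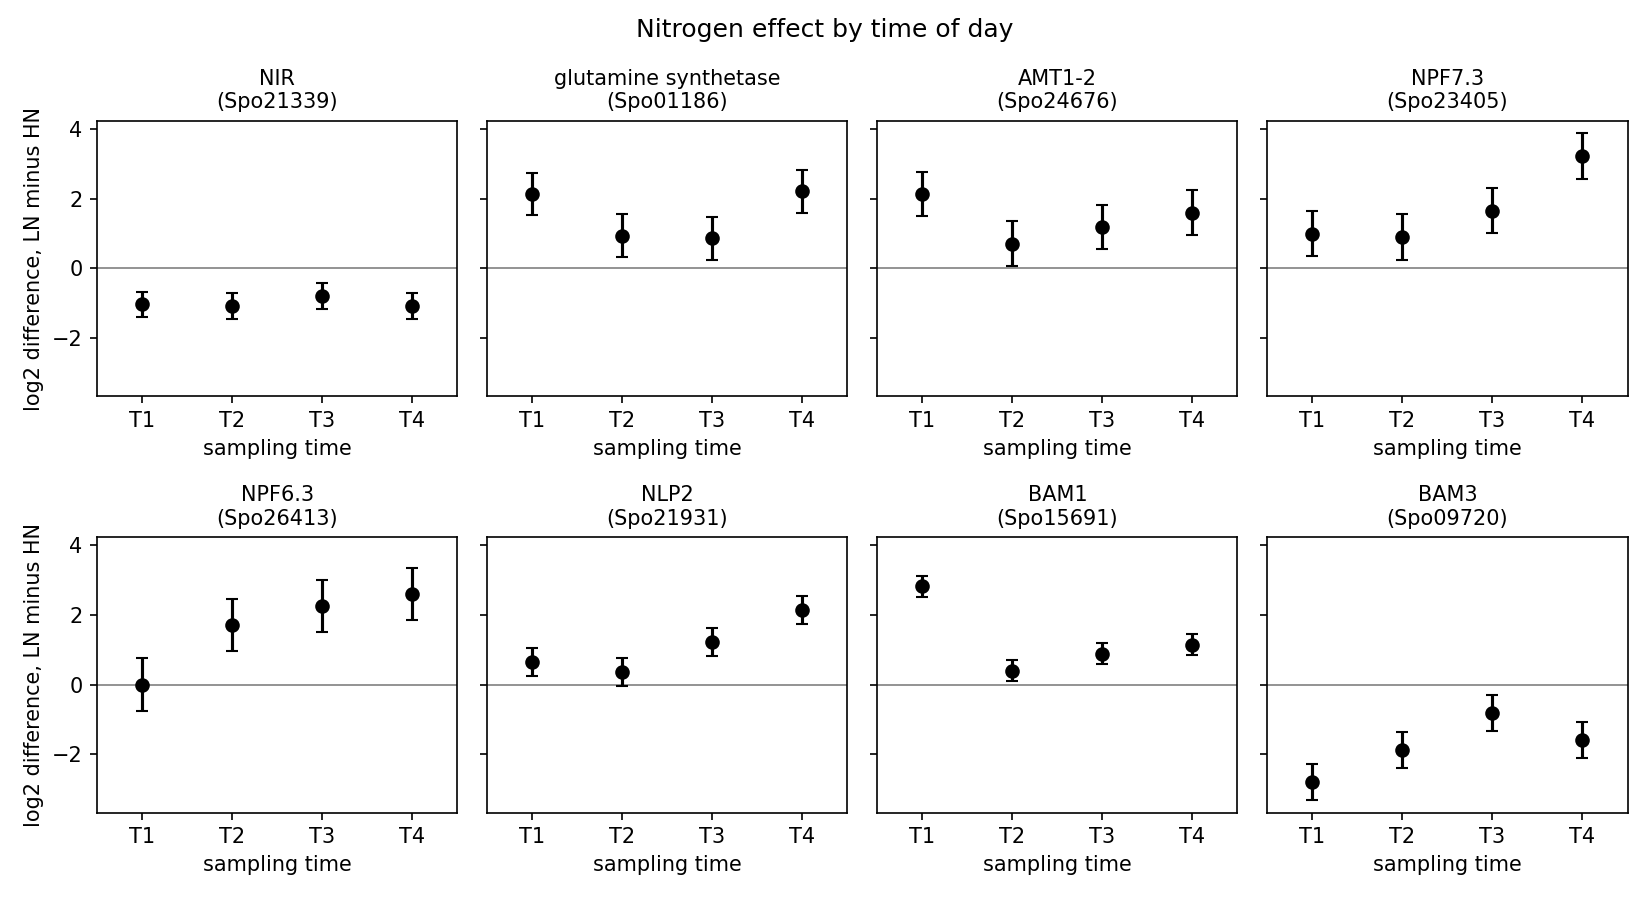
Log2 difference LN minus HN of 8 genes of nitrogen and starch metabolism at each of the 4 times; points are limma estimates on log2(FPKM + 1) from 3 plants per group, and error bars are 1 SE. Averaged over the times, NIR and BAM3 lie below 0, and AMT1-2, NPF7.3, NPF6.3, BAM1, NLP2 and the glutamine synthetase Spo01186 lie above 0.

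Single genes of starch and sugar metabolism changed, while starch breakdown (3 of 32 rose and 3 fell, 3 and 4 when adjusted over the list alone) and sucrose metabolism and transport (5 of 35 rose and 4 fell, 6 and 5) had no list call (camera adjusted p = 0.96 for both). BAM1 (Spo15691) and BAM3 (Spo09720), both plastid beta-amylases that release maltose from starch, went opposite ways, by 1.31 (SE 0.15, adjusted p = 0.00017) and -1.77 (SE 0.26, adjusted p = 9e-04). The sugar transporter SWEET14 (Spo08933) fell by 2.04 and the trehalose-phosphate phosphatase TPPF (Spo11422) by 1.41. Of 22 antenna genes 3 fell and 0 rose (5 and 0 when adjusted over the list alone, median -0.47), with LHCB5 (Spo01700) at -0.86, and of 46 photosystem genes 7 fell and 1 rose (9 and 1). The camera adjusted p values were 0.010 and 0.033, and 0.99 with an estimated correlation; the antenna value was 0.060 without LN_T1 replicate 2, and the photosystem value lay between 0.051 and 0.14 without HN_T1 replicate 3, HN_T2 replicate 2, HN_T3 replicate 2, HN_T4 replicate 2, LN_T1 replicate 2, LN_T1 replicate 3, LN_T3 replicate 2 or LN_T4 replicate 3. A small subunit of Rubisco, RBCS2 (Spo21477), fell by 1.26. Of 61 heat shock genes 17 rose and 3 fell (18 and 3 when adjusted over the list alone, median 0.22, camera adjusted p = 0.00014), with HSP18.1 (Spo28313) at 1.89 and HSP70 (Spo06975) at 1.71. This call was lost with an estimated correlation (adjusted p = 0.99 with an estimated correlation). Of the 116 defence genes 16 rose and 9 fell, without a list call (19 and 13 when adjusted over the list alone, camera adjusted p = 0.23).

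Among clock genes, 4 of 24 fell, 1 rose and 19 did not pass (4 and 1 when adjusted over the list alone), and EFL4 (Spo25307), of the ELF4 family, fell by 0.62. COL13 (Spo09904) of the CONSTANS-like family rose by 0.97 (SE 0.10, adjusted p = 0.00016). The largest falls among named proteins with 1 direction at all 4 times included those of Spo12226, a xyloglucan endotransglucosylase of the cell wall (-3.23), TSJT1 (Spo14130, -3.01), Spo14333, a WAT1-related transporter (-2.74), and BXL1 (Spo06262), a cell wall xylosidase (-2.60). SE2 (Spo22294), an acidic endochitinase, rose by 2.47 and the thaumatin-like tlp (Spo00732) by 2.21. Over all genes 2995 passed (16.5%), 1434 higher and 1561 lower in LN, and 339 of them changed by at least 2-fold. The balance of directions turned among those 339 (198 higher and 141 lower), with a common sum of FPKM (1282 higher and 1081 lower) and with array weights (2222 higher and 2202 lower). Markers of phloem and xylem (3 of 27 fell, 0 rose, camera adjusted p = 0.40) and of stomata (1 of 9 fell, 0 rose, camera adjusted p = 0.51) did not move as lists.

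At the end of dark, 15 of 61 heat shock genes were higher in LN and plastid beta-amylases changed in both directions. HSFB2A (Spo12958) and HSF30 (Spo06105), both heat stress transcription factors, rose by 2.67 (SE 0.36, adjusted p = 0.00034) and 2.49 (SE 0.39, adjusted p = 0.0011). HSP70-4 was at 0.715 ± 0.231 FPKM in HN and 31.9 ± 27.2 in LN, a log2 change of 3.96 with a spread in LN close to its mean. Of the 61 heat shock genes, 15 rose and 2 fell (22 and 2 when adjusted over the list alone, median 0.56, camera adjusted p = 2.8e-06). This call was lost with an estimated correlation (adjusted p = 0.99 with an estimated correlation). The fry test asks another question, whether the members move on balance, without comparing them with other genes. It gave an adjusted p of 0.0022. Of all 18110 tested genes, 4736 had an unadjusted p under 0.05 at this time, so fry does not show that the list stands out. BAM1 rose by 2.82 (SE 0.30, adjusted p = 4.7e-05) and BAM3 changed by -2.80 (SE 0.52, adjusted p = 0.0034). CKX5 (Spo01919), a cytokinin dehydrogenase, rose by 3.63 and AAP6 (Spo02077), an amino acid permease, by 1.32. SWEET14 fell by 3.12 and AAH2 (Spo00912), an allantoate deiminase of ureide breakdown, by 1.01.

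Among nitrogen genes at this time, NPF1.2 (Spo25687) rose by 2.01 and AMT3-1 by 2.13, the latter with an adjusted p of 0.080 without HN_T1 replicate 1 and 0.071 without LN_T1 replicate 3. Of the assimilation genes, 4 rose and 3 fell (6 and 4 when adjusted over the list alone). Of the clock genes, 1 rose and 2 fell (3 and 3 when adjusted over the list alone), with EFL4 falling by 0.94. Photosystem (2 of 46 fell, camera adjusted p = 0.0093) and Calvin cycle genes (1 of 26 fell, camera adjusted p = 0.014) were lower as lists, both at 0.99 with an estimated correlation; the photosystem value was 0.21 without HN_T1 replicate 3 and 0.080 without LN_T1 replicate 2, and the Calvin cycle value 0.16 and 0.37. In total 1805 genes passed, 924 higher and 881 lower. The count rests on single plants: it was 676, 1097 and 890 without HN_T1 replicates 1, 2 and 3, and 389 without LN_T1 replicate 3. It was 316 with only the 6 libraries of this time in the fit and 3351 without the 3 libraries farthest from their groups. Those 3 were picked for a low correlation with their own groups. Leaving them out tends to lower the shared estimate of spread, so a higher count is partly built in. Rescaling to a common sum of FPKM moved the share of higher calls from 51.2% to 69.8%. Lower calls outnumbered higher ones without LN_T1 replicate 2 (1260 higher and 1402 lower), without the 3 farthest libraries (1635 and 1716), with a mean FPKM of at least 5 (701 and 846) and with voom (795 and 819).

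In the middle of light and at the end of light, hardly any gene passed. In the middle of light 1 gene did, Spo08947, a small chloroplast heat shock protein, chosen after its values were seen, at 0.36 ± 0.0793 FPKM in HN and 6.03 ± 3.71 in LN, a log2 change of 2.24 (SE 0.32, adjusted p = 0.017). At the end of light the WAT1-related Spo14333 fell, from 30.6 ± 18.9 in HN to 0.751 ± 0.466 in LN, a log2 change of -4.03 (SE 0.62, adjusted p = 0.047). Genes of cell division and histones were higher as a list in LN in the middle of light (0 of 88 passed, 1 rose and 1 fell when adjusted over the list alone, median 0.43, camera adjusted p = 0.0001). The nitrate transport list was higher in LN at the end of light (0 of 55 passed, 1 rose when adjusted over the list alone, median 0.25, camera adjusted p = 0.010). Both values were 0.99 with an estimated correlation. The nitrate transport value was 0.059 without HN_T3 replicate 3 and 0.21 without LN_T3 replicate 2. Starvation peptides and glutaredoxins were lower as a list at the end of light (0 of 28 passed, 1 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.014, and 0.99 with an estimated correlation), a call that ended without LN_T3 replicate 2 (0.22) and among members with a mean FPKM of at least 5 (0.082). At an unadjusted p under 0.05, 1698 and 1340 genes passed, against 906 expected by chance, and voom on the recovered fragments called 0 and 0. The count for the middle of light was 0 without HN_T2 replicate 3, LN_T2 replicate 1 or LN_T2 replicate 2, and 3 without HN_T2 replicate 2. Without HN_T2 replicate 1 the adjusted p of Spo08947 was 0.061. With a pseudocount of 0.1 it was 0.32 for Spo08947 and 0.34 for Spo14333. The count for the end of light was 10 without LN_T3 replicate 3 and 0 without HN_T3 replicate 1, 2 or 3 or LN_T3 replicate 1 or 2. Without the 3 libraries farthest from their groups the counts were 25 and 171.

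In the middle of dark, 2 of 22 antenna genes were lower in LN and a nitrate transporter and a nitrate-responsive regulator higher. Spo03024 stood at 529 ± 211 FPKM in HN and 55.1 ± 55.5 in LN, a log2 change of -3.93 (SE 0.74, adjusted p = 0.028), and Spo03025 at 41.2 ± 6.7 and 6.81 ± 8.45 (-3.06). Of the 22 antenna genes 2 fell, 0 rose and 20 did not pass (11 and 0 when adjusted over the list alone, median -1.0, camera adjusted p = 2.9e-05). Of the 22, 6 were lower in every LN than in every HN library. Chance gives 5% for a single gene, but these genes can shift together within a library, so the 6 are not independent. The call was lost with an estimated correlation (adjusted p = 0.99 with an estimated correlation); without LN_T4 replicate 3, whose mean antenna level of 6.28 was the lowest of the 24 libraries, the list median was -0.44 and the camera adjusted p 0.0049. NPF7.3 rose by 3.23 (SE 0.65, adjusted p = 0.037) and NLP2 by 2.15, while the glutaredoxin GRXS1 (Spo09893) fell by 3.42 and a DnaJ chaperone (Spo07785) by 2.55. Spo00705, a pathogenesis-related protein, rose by 5.08. Each of these calls ended when a library was left out. Without HN_T4 replicate 2, HN_T4 replicate 3 or LN_T4 replicate 3, the adjusted p of Spo03024, Spo03025, NPF7.3, NLP2 and Spo00705 lay between 0.12 and 0.28. Without HN_T4 replicate 3 it was 0.056 for GRXS1 and for Spo07785, which was also at 0.057 without LN_T4 replicate 3. Without HN_T4 replicate 1 it was 0.052 for Spo03025 and 0.057 for NPF7.3, and without LN_T4 replicate 1 it was 0.061 for Spo03025. With the replicate number as a block it was 0.051 for Spo03025 and 0.054 for Spo00705.

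The nitrate transport list (1 of 55 rose, 5 when adjusted over the list alone, median 0.37, camera adjusted p = 0.012) was higher in LN in the middle of dark. Chlorophyll synthesis (0 of 26 passed, 9 fell and 1 rose when adjusted over the list alone, camera adjusted p = 0.021) and cell division and histones (0 of 88 passed, 1 rose when adjusted over the list alone, camera adjusted p = 0.0041) were lower. Starvation peptides and glutaredoxins were lower too (3 of 28 fell, 8 fell and 2 rose when adjusted over the list alone, camera adjusted p = 0.014). All 4 values were 0.99 with an estimated correlation, and the last was 0.42 among members with a mean FPKM of at least 5. Without LN_T4 replicate 3 the first 3 were 0.15, 0.20 and 0.088. The chlorophyll value was 0.16 without HN_T4 replicate 2 and 0.053 without LN_T4 replicate 1, and the histone value 0.074 without LN_T4 replicate 1. Photosystem genes (0 of 46 passed, 0 when adjusted over the list alone, camera adjusted p = 0.038) were lower and autophagy genes (0 of 21 passed, 0 when adjusted over the list alone, camera adjusted p = 0.047) higher, both at 0.99 with an estimated correlation. The photosystem value was 0.13 without HN_T4 replicate 2, 0.062 without LN_T1 replicate 2, 0.050 without LN_T3 replicate 2 and 0.64 without LN_T4 replicate 3. The autophagy value was 0.21 without HN_T4 replicate 2, 0.13 without LN_T4 replicate 1 and 0.096 without LN_T4 replicate 3. It lay between 0.050 and 0.058 without HN_T2 replicate 2, HN_T3 replicate 2, LN_T1 replicate 2, LN_T1 replicate 3 or LN_T2 replicate 2. It was 0.057 with a pseudocount of 0.1 and 0.086 with a common sum of FPKM. At this time 67 genes passed, 24 higher and 43 lower, and 3196 did at an unadjusted p under 0.05. The count was 5 and 0 without HN_T4 replicates 2 and 3, 111, 233 and 6 without LN_T4 replicates 1, 2 and 3, and 0 with only the 6 libraries of this time in the fit. The balance of directions turned without HN_T4 replicate 1 (49 higher and 42 lower) and without LN_T4 replicate 2 (133 higher and 100 lower), and with a pseudocount of 0.1 (28 higher and 25 lower). With array weights it was near even (209 higher and 207 lower).

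**Figure D3:**
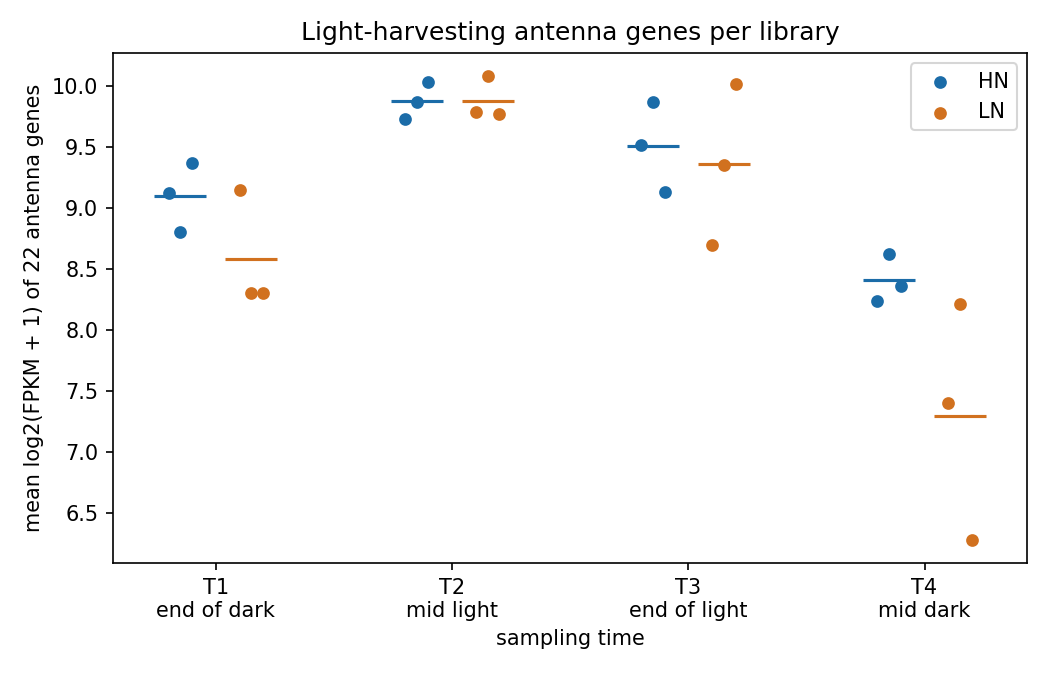
Mean log2(FPKM + 1) of the 22 light-harvesting antenna genes in each library, by sampling time (T1 end of dark, T2 middle of light, T3 end of light, T4 middle of dark); each point is a plant and the bars are group means. In the middle of dark the LN plants lie at 7.40, 8.21 and 6.28 and the HN plants at 8.24, 8.62 and 8.36.

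Whether the nitrogen effect itself differed between times was tested with an interaction term. It passed for 15 genes, and 1964 had an unadjusted p under 0.05. The 8 with named proteins and a mean FPKM of at least 5 each had their largest nitrogen effect at the end of dark. CUT1 (Spo21466), a 3-ketoacyl-CoA synthase of wax synthesis, differed by 1.96 on the log2 scale at the end of dark and by -0.11, 0.32 and 0.67 at the later times (adjusted p = 0.016). CPRF1 (Spo01619), a transcription factor, differed by 3.30, -0.13, 0.32 and 0.54 (adjusted p = 0.036). Effects at the end of dark were also positive for MNS3 (Spo08978), BC10 (Spo08991), XBOS32 (Spo04561) and the aspartic proteinase RAP (Spo01909), and negative for abhd17c (Spo08820) and PRA1F2 (Spo30007), with adjusted p between 0.036 and 0.048. The adjusted p of CUT1 was 0.11 without HN_T1 replicate 1 and 0.11 without LN_T1 replicate 3, and the other 7 calls each ended when any of 11 to 20 of the libraries was left out (adjusted p up to 0.19). With the replicate number as a block, XBOS32 was at 0.073 and MNS3 and BC10 at 0.057. A block for the number within each nitrogen level left 5 genes in the interaction, 4 of them among the 15. With a pseudocount of 0.1 the 7 lay between 0.059 and 0.061, and with a common sum of FPKM RAP, XBOS32, abhd17c, BC10 and PRA1F2 lay between 0.061 and 0.088. No member of the 32 lists fixed before the data were examined passed. The difference between the 1805 genes at the end of dark and the 1, 1 and 67 genes at the other times is not shown gene by gene. The count of 15 was 0 without LN_T1 replicate 3, 1 without HN_T1 replicate 1, 2 without HN_T1 replicate 3 or HN_T4 replicate 2, and 3 without HN_T4 replicate 3 or LN_T2 replicate 1. It lay between 5 and 9 without HN_T3 replicates 1, 2 or 3, HN_T2 replicate 2, LN_T2 replicate 3, LN_T3 replicate 2 or LN_T4 replicate 1. It was 23 without LN_T1 replicate 2, 30 without HN_T2 replicate 3, 53 without LN_T3 replicate 3 and 101 without LN_T1 replicate 1.

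**Figure D4:**
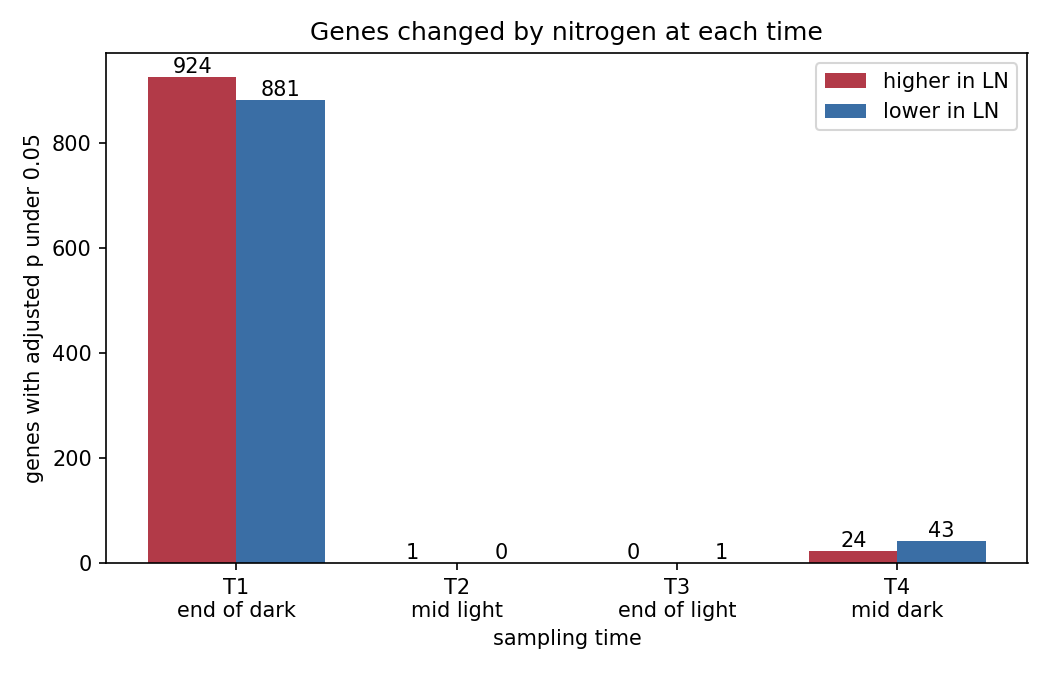
Number of genes past an adjusted p of 0.05 for LN against HN at each time (3 plants against 3), split into higher and lower in LN. The bars start at 0, and the counts are 1805 at the end of dark, 1 in the middle of light, 1 at the end of light and 67 in the middle of dark.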

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

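The shares of genes beyond the daily range and the rescaled medians in HN were tests set before their results were seen. The contrasts, the list tests, the fits of the compared groups alone and those with a library left out were also planned. Their use to weigh explanations was chosen after the results were seen. So was every other test here, the regroupings of libraries included.

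Nitrogen changed 1805 genes at the end of dark and 1, 1 and 67 at the later times. The root mean square of the nitrogen effect over genes was 0.62, 0.41, 0.41 and 0.55 on the log2 scale from T1 to T4, against 0.35 from residual spread alone. A later collection of the LN plants would keep effects within the full daily range of HN. Of the 1805, 19.8% (357 genes) exceeded the range of the HN group means by over 2 SE. That range covers the sampled times only, and a gene can peak between them, so this test cannot decide. A later collection stays open as a cause. The slope of the clock genes' nitrogen effect along the HN day was 0.09 (SE 0.041) at the end of dark. That SE is across genes, which are not independent. A larger spread at the end of dark than the shared estimate is argued against as the whole cause by 316 genes in a fit of those 6 libraries alone (1, 0 and 0 at the other times). Such a spread may still be part of the cause, since the median SD was highest in LN at the end of dark (0.323, and 0.233 in HN). The median SD was close to this at the end of light (0.309 in LN and 0.225 in HN), where 1 gene passed, so it does not set the end of dark apart. A biological difference at the end of the night remains a hypothesis; the 10 splits of the 6 libraries are too few for a share under 0.05 (1805 genes in the real split, 66 in the highest other), and the 3 other splits that part all same-number pairs gave at most 0.

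The antenna list was lower in LN in the middle of dark (median -1.0), with 2 of 22 genes passing; both ended without HN_T4 replicate 2, HN_T4 replicate 3 or LN_T4 replicate 3 (adjusted p between 0.14 and 0.28), and the list call was lost with an estimated correlation (0.99). With the preset correlation the list call did not rest on LN_T4 replicate 3 alone, since the camera adjusted p was 0.0049 without it, although the median was then -0.44. Reads shared between near-identical copies would leave the family's sum unchanged and stay open, since the log2 summed antenna FPKM differed by -1.28 (SE 0.64), and by -0.70 (SE 0.42) without LN_T4 replicate 3, within 2 SE of a difference near 0. Whether the LN plants were collected at another point of the dark cannot be told apart from a nitrogen effect, since the clock genes' slope along the HN day was 0.06 (SE 0.028), between the bounds set for either reading. The 10 splits for the middle of dark are too few for a share under 0.05 (67 genes in the real split, 0 in the highest other).

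Scaling the libraries to a common sum of FPKM turned the balance of calls from the middle of dark to the middle of light, with a median change over genes of -0.35 in HN and -0.22 in LN. A few abundant genes may set that sum: the 100 most abundant genes held 45.4% of it in the middle of light and 34.5% in the middle of dark in HN. Leaving them out moved the median to -0.13 in HN, between the bounds set, and to -0.05 (SE of the library scaling 0.028) in LN, within the bound of 0.1 that this explanation needs, so how much of the shift they explain in HN stays open. A larger weight of short genes in a sum of FPKM is argued against as the whole cause by a median of -0.25 with the sum of fragments in HN (SE 0.059) but stays open in LN, at -0.15 (SE 0.077). No biological explanation was tested.

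The nitrogen effect differed between times for 15 genes by the interaction test. Chance cannot be excluded, and the regroupings of the libraries within their times cannot decide it. Of 100 groupings, the real one included, 10 gave at least as many genes, with 1173 in the highest other. A regrouping can keep the nitrogen split at 1 time and break it at the others. A nitrogen effect shared by the times then appears as an interaction. A regrouping that calls several times the real count may reflect this or a structure of the samples. The libraries LN_T1 replicate 2, LN_T3 replicate 3 and LN_T4 replicate 3 had the lowest mean correlations with their groups (0.9229, 0.9061 and 0.9136). Of the 15 genes, CUT1 (Spo21466) had an adjusted p of 0.016, and CPRF1 (Spo01619), abhd17c (Spo08820) and PRA1F2 (Spo30007) each had 0.036. MNS3 (Spo08978) had 0.040, and RAP (Spo01909), XBOS32 (Spo04561) and BC10 (Spo08991) each had 0.048.

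If each library is an independent plant, the regroupings argue against chance for the nitrogen effect averaged over the times (2995 genes in the real grouping, 1 in the highest other of 100). The same holds for time of day in HN (7053, highest other 4441) and in LN (5197, highest other 1724). Whether a replicate number follows 1 plant over the day is not known, and the regroupings do not cover that case. For the remaining comparisons the 10 splits are too few for a share under 0.05. The real and highest other counts were 1 and 0 for nitrogen in the middle of light, and 1 and 8 at the end of light. They were 4284 and 1 in HN and 1387 and 0 in LN for the middle of light against the middle of dark, and 5925 and 0 in HN and 4706 and 10 in LN for the end of light against the end of dark.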

How the results depend on the processing

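The fits without the 3 libraries farthest from their groups, with array weights, with voom and with a replicate block within the end of dark were chosen after seeing the data. The others were planned. Leaving out libraries picked for their distance from their groups tends to lower the shared estimate of spread. Higher counts in that fit are therefore partly built in and are no independent check. The counts for averaged nitrogen, time of day in HN and the end of light against the end of dark in HN stayed within 1.5 times of their values under every alternative except the 2-fold threshold. With a pseudocount of 0.1, nitrogen called 0 genes in the middle of light, 0 at the end of light and 2 in the interaction, and the share of higher calls in the middle of dark went from 35.8% to 52.8%. Without a filter the counts were 3, 0, 44 in the middle of dark and 28 in the interaction, and with a mean FPKM of at least 5 the middle of light had 0. With only the compared groups in the fit, nitrogen called 316 genes at the end of dark and 0 at the end of light and in the middle of dark, time of day 7967 in HN and 2736 in LN, the middle of light against dark 3750 and 432, and the end of light against dark 6491 and 1583. Robust moderation gave 2 in the middle of light and 0 at the end of light. A 2-fold threshold left 938 genes at the end of dark, 339 for averaged nitrogen, 4236 and 3236 for time of day in HN and LN, 1952 and 744 for the middle of light against the middle of dark, and 2944 and 2398 for the end of light against the end of dark. Without the 3 farthest libraries the nitrogen counts from T1 to T4 were 3351, 25, 171 and 11, the interaction 306 and the LN middle of light against dark 2129; with array weights they were 3427, 6, 68, 416, 262 and 2506. Voom gave 0, 0 and 33 at T2, T3 and T4 and 2 in the interaction. With 1 library left out, the ranges were 389 to 2662 at the end of dark, 0 to 3 in the middle of light, 0 to 10 at the end of light, 0 to 233 in the middle of dark, 2071 to 3860 for averaged nitrogen and 0 to 101 for the interaction. They were 2534 to 4555 (HN) and 470 to 1420 (LN) for the middle of light against dark, 4445 to 5266 (HN) and 3176 to 4718 (LN) for the end of light against dark, and 26 to 42 for the list calls, of which 34 fell to 0 with an estimated correlation. Of the 34, 14 held whichever library was left out.

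With the replicate number as a block, nitrogen called 1593 genes at the end of dark, 1, 1 and 51 at the later times, 2780 on average and 11 in the interaction; time of day called 6777 in HN and 4871 in LN, the day contrasts 4135, 1192, 5762 and 4513, and the lists 32. A block within the end of dark alone, where same-number libraries deviate together, gave 2100 and changed no list call there and no call of the genes named for that time. A block for the number within each nitrogen level gave 5 in the interaction, and no other count moved by over 1.5 times with a block. Of 48 same-number pairs of libraries, 18 correlated best with their own number. Each library was compared with the 3 numbers of the other group, so unpaired libraries would match in about 1 of 3 cases. The 18 are therefore near what chance gives. The cause of the differences between settings was not tested. Among single genes, the sign turned only for nitrogen effects near 0 in the middle of light, at 0.04 for CPRF1 (Spo01619) without HN_T2 replicate 1 and 0.09 without LN_T2 replicate 1 (range -0.44 to 0.09), and at 0 for CUT1 (Spo21466) without HN_T2 replicate 3 (range -0.21 to 0). Median-of-ratios scaling, which the deposited values already carry, tests little: 1804 genes passed at the end of dark, 2993 for averaged nitrogen and 1390 for the LN middle of light against dark.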

Other observations

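The test of a clock shift below was chosen after the result was seen. A clock phase shifted the same way at every time is a possible explanation for differences in clock genes between LN and HN, and would give the slope of their nitrogen effect along the HN day 1 sign at all 4 times. Over 24 clock genes the slope was 0.09 (SE 0.041) at the end of dark and 0.02 (SE 0.023) in the middle of light. It was -0.07 (SE 0.020) at the end of light and 0.06 (SE 0.028) in the middle of dark, which argues against a shift of 1 size and direction; the SE is across genes, which are not independent.

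Some libraries stood apart in single groups of genes. The mean log2 level of transcripts named after organelle genes, a list added after seeing the data, was 4.20 in LN_T3 replicate 1. Genes of cell division and histones had means of 3.02, 3.31 and 4.31 in LN_T3 replicates 1, 2 and 3. In the middle of dark they were at 3.17, 4.06 and 2.94 in LN and at 3.68, 4.03 and 3.84 in HN. The phloem and xylem markers lay at 2.91, 2.41 and 1.83 in the LN libraries of the middle of dark.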
